A study of Mus musculus with 12 samples.

How the data were processed

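RNA of mouse embryonic fibroblasts was sequenced in 12 libraries, in 4 groups of 3. The cells, of strain C57BL/6, carried FUW-OSKM and FUW-M2rtTA, lentiviral constructs for the doxycycline-induced expression of Oct4 (gene symbol Pou5f1), Sox2, Klf4 and Myc. They also carried short hairpins that were scrambled, against Trim28, or against Trim28 and Setdb1. The uninduced cells had the scrambled hairpin. Per the labels' protocols, cells were kept for 7 days on irradiated feeder fibroblasts in embryonic stem cell medium, RNA was extracted with Trizol, and libraries were made with a TruSeq RNA kit. Groups and replicate numbers were taken from the sample titles. The labels do not say that the 3 replicates of a group came from separate cultures or embryos, so p-values measure only the spread between these samples, which may be technical.

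The values used are whole-number read counts per gene for 24207 genes, as the authors deposited them, with an Ensembl identifier and coordinates for each gene. Per the submitters' processing notes, reads were processed with TopHat2 2.0.12, Bowtie 1.1 and HTSeq, whose version is not stated. The genome build is not given in the sources used here, and coordinates are printed as the deposited table gives them. In a mouse annotation of the build GRCm38, 23882 of the 24207 identifiers were found, 23873 of these at an overlapping place and 18779 with the same start. Every gene in the table had at least 1 read, and the table had no summary line for unassigned reads. The counting is not stated to use strand, so reads of overlapping or antisense genes cannot be told apart. Counts of genes with near-identical copies, such as the protocadherins, are uncertain. Reads of the 4 vector-borne factors cannot be told from those of the cells' own genes where both share coding sequence. Total counts ran from 11906701 to 19191649 per library, so 3 counts in 1 library correspond to 0.156 to 0.252 CPM (counts per 1e6 counts).

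Before the data were examined, the groups, tests, gene lists, the rule for naming genes and the alternative settings were fixed. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM factors, model with 1 term per group over all 12 libraries), with limma 3.58.1 for gene lists. Genes were kept by edgeR's expression filter with a minimum count of 10 and a minimum total of 15, which left 14520 genes. A gene rose or fell where its Benjamini-Hochberg adjusted p was under 0.05 over these genes. Of the 4 comparisons, the first set induced against uninduced cells, both with scrambled hairpins. In induced cells, the others set the Trim28 hairpin against the scrambled hairpin, both hairpins against the scrambled hairpin, and both hairpins against the Trim28 hairpin alone. This last comparison is also the test of the difference between the single and the double knockdown. Log2 fold changes carry standard errors from the model (SE), and CPM values, normalised with the TMM factors, are means ± SD over 3 libraries.

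A gene with 0 counts in a group is given as at least so many fold higher in the other, against a floor of 3 counts over the group, and a gene with 1 to 3 counts over a group as a ratio with a 95% counting interval. Such floors and intervals cover counting error only, because reads without molecular identifiers are not independent molecules. The genes named in each comparison are Trim28, Setdb1 and the 4 factors. To these come the 6 largest rises and 6 largest falls among changed genes with a mean of at least 1 CPM in the higher group and no overlap between the libraries of the 2 groups, leaving out predicted genes, clone names and pseudogenes. Named last are, in each list, up to 3 members with the smallest p in the majority direction and 1 in the other. Chance alone leaves 10% of genes without overlap between 3 and 3 libraries. A gene named in 1 comparison may be followed through the others, and genes outside the rule are said to be so. Some genes that the rule takes are not reported here.

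The 25 lists, written from general knowledge, were the reprogramming factors, the knockdown targets, the pluripotency network, epithelial and mesenchymal genes, imprinted genes, two-cell-stage genes, germline genes, clustered protocadherins, heterochromatin machinery, interferon response, proliferation, and p53 and senescence genes. Markers of other cell types formed the macrophage, endothelial, muscle, neural, keratinocyte, trophoblast, primitive endoderm and adipocyte lists. Signs of sample identity and RNA quality formed the sex-linked, mitochondrial-encoded and nuclear long noncoding lists, and all genes named Zfp with a number formed a zinc finger list of 367 members in the table, which includes genes without the KRAB domain that binds Trim28. Some genes, among them Dcn, Perp, Peg10, Meg3 and Tex19.1, are in more than 1 list. Each comparison's 19 lists of at least 5 tested genes went through camera on log2 CPM (prior count 2, preset correlation 0.01, two-sided), with Benjamini-Hochberg adjustment over those lists, and again with an estimated correlation between genes.

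Correlations of log2 fold changes between comparisons were taken across the 14520 genes, which are not independent replicates, and 4 such relations were computed. Because 3 of them share control libraries, unchanged groups were simulated 50 times. They gave the correlation and covariance that shared libraries produce when each gene varies independently. Shifts of many genes together in 1 library were not simulated. The tests were checked on simulated counts in which 200 genes were changed by log2 0.5, 1 or 2. For a log2 change of 1, 77.6% of changed genes were recovered in the induction, 89.6% in the Trim28 knockdown, 85.1% in the double knockdown and 79.1% for the added Setdb1 hairpin, with 10 of 165, 10 of 168, 9 of 157 and 19 of 173 calls false. In each simulation the 1 list that had been moved was called. Its genes were also drawn independently, so this does not check camera's preset correlation. Libraries with the same replicate number deviated together from their group means in the induced controls and the double knockdown (r = 0.141 to 0.31, over 0.1 in 3 of 3 pairs). The numbers were therefore taken, from the data and not from the labels, to pair the samples of that comparison. Its main results still come from the fit without pairs, and a block by replicate number was run as an alternative. In each of the other comparisons 1 of 3 pairs was over 0.1. Settings were also varied: RLE size factors, DESeq2 1.42.0, limma-voom, no or a stricter low-count filter (1 CPM in 6 libraries), the 2 compared groups alone, the replicate number as a block, a minimum fold change of 2, and each library left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.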

Results

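Expression was measured on day 7 in mouse embryonic fibroblasts, connective tissue cells that the factors Oct4, Sox2, Klf4 and Myc (OSKM) can turn towards pluripotent stem cells. The 12 libraries fell into 4 groups of 3: uninduced cells with a scrambled hairpin, and OSKM-induced cells with a scrambled hairpin, with a hairpin against Trim28, or with hairpins against Trim28 and Setdb1. Trim28 is a corepressor that zinc finger proteins bring to DNA, and Setdb1 is a histone H3 lysine 9 methyltransferase that acts with it. The libraries held 11906701 to 19191649 counted reads, and between 17799 and 19353 genes had a read. Mitochondrial transcripts took 1.78% to 2.37% of reads. The highest shares were in replicate 2 of the induced controls and replicate 3 of the uninduced cells. The first principal component, with 78.9% of the variance, placed the uninduced libraries at 117 to 120. Induced controls lay there at -49.2 to -35.2, the Trim28 knockdown at -52.4 to -45.4 and the double knockdown at -29.9 to -16.2. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 1.96 to 18.8), so no 2 libraries were counted as 1, which does not show that they came from separate cultures. The labels do not say whether feeder fibroblasts were removed before RNA was extracted.

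The hairpin targets were read first. Trim28 (ENSMUSG00000005566, chromosome 7, 13024152 to 13031035) stood at 328 ± 38.3 CPM (SD, n = 3) in the induced controls, 58.5 ± 5.95 with its hairpin and 103 ± 6.41 with both hairpins. Its log2 change was -2.49 ± 0.10 (SE, n = 3 per group, edgeR quasi-likelihood adjusted p = 9.61e-11) in the Trim28 knockdown. In the double knockdown it was -1.67 ± 0.099 (adjusted p = 5.04e-09). Setdb1 (ENSMUSG00000015697, chromosome 3, 95323525 to 95357202) rose from 81.2 ± 4.27 to 122 ± 1.36 CPM with the Trim28 hairpin, a log2 change of 0.59 ± 0.085 (adjusted p = 8.24e-05). With both hairpins Setdb1 stood at 63.1 ± 8.21 CPM. This was -0.36 ± 0.086 on the log2 scale against the induced controls (adjusted p = 0.00363) and -0.95 ± 0.085 against the Trim28 knockdown (adjusted p = 2.53e-06). In that same comparison Trim28 itself was higher by 0.82 ± 0.10 (adjusted p = 4.3e-05). The libraries with both hairpins thus held less Setdb1 and more Trim28 transcript than those with the Trim28 hairpin alone. Uninduced cells had 249 ± 24.9 CPM of Trim28 and 60.7 ± 4.29 of Setdb1, and both targets rose with induction, by 0.40 ± 0.096 and 0.42 ± 0.086 (2 rose adjusted over the list alone).

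All 4 reprogramming factors rose with induction, Pou5f1 (the gene of Oct4), Sox2, Klf4 and Myc by 4.64 ± 0.14, 3.87 ± 0.21, 1.83 ± 0.10 and 2.51 ± 0.12 on the log2 scale (SE, n = 3 per group, 4 rose adjusted over the list alone). With the Trim28 hairpin none of the 4 passed the edgeR test, with log2 changes of 0.24, 0.24, 0.08 and 0.12 and adjusted p = 0.123, 0.333, 0.593 and 0.472. Pou5f1 alone had an unadjusted p under 0.05 (0.0431), and DESeq2 and limma-voom called none of the 4 either. With both hairpins all 4 fell against the induced controls, by log2 -0.41 ± 0.11, -0.54 ± 0.17, -0.54 ± 0.096 and -0.42 ± 0.11 (4 fell adjusted over the list alone). Against the Trim28 knockdown the changes were -0.65 ± 0.11, -0.78 ± 0.17, -0.62 ± 0.096 and -0.53 ± 0.11 (4 fell adjusted over the list alone). The fall of Sox2 against the induced controls (adjusted p = 0.0237) was lost in 5 of 13 alternatives (range 6.07e-10 to 0.116). It stood at adjusted p = 0.0758 with DESeq2, 0.0503 and 0.101 without replicate 1 or 3 of the induced controls, and 0.116 and 0.0515 without replicate 1 or 3 of the double knockdown. Vector and endogenous transcripts of the factors cannot be told apart in these counts.

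**Figure D1:**
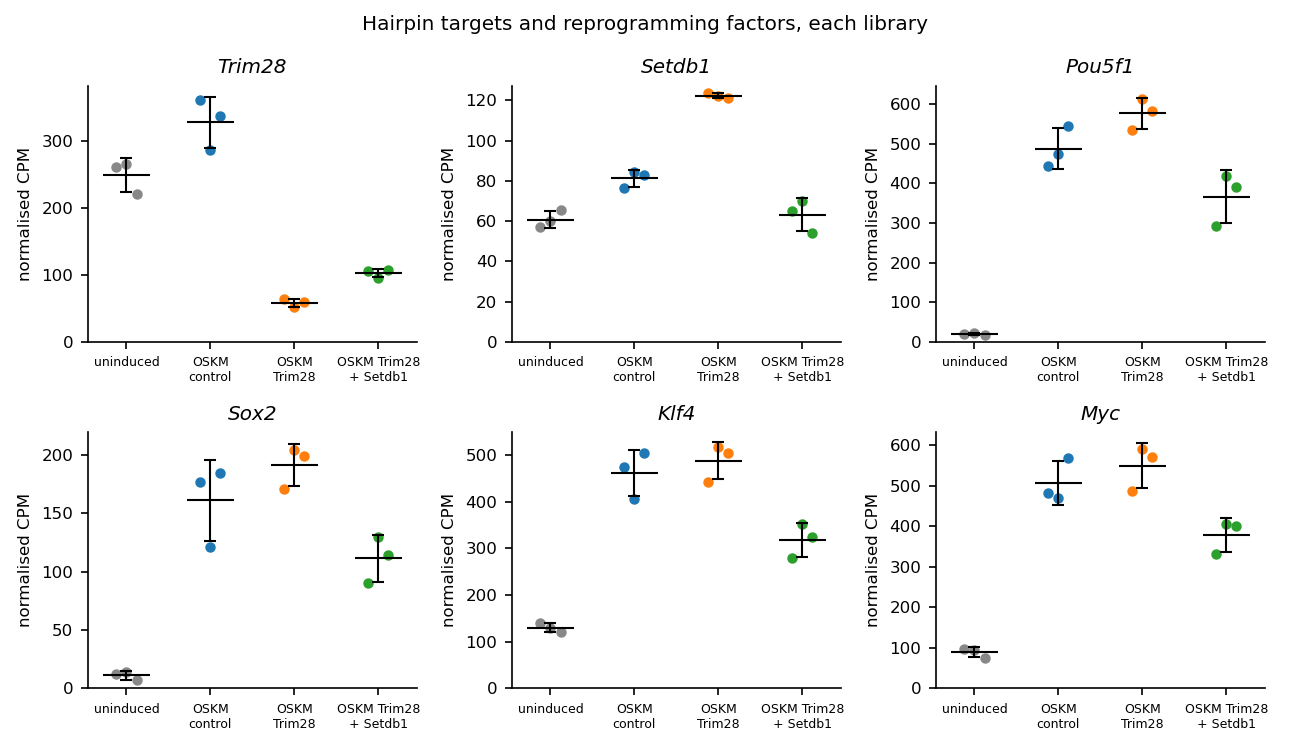
Normalised CPM of the 2 hairpin targets and the 4 factors in each library (points, 3 per group), with group means and SD as bars, on linear axes from 0. Trim28 falls from 328 ± 38.3 CPM in the induced controls to 58.5 ± 5.95 with its hairpin and 103 ± 6.41 with both, and Setdb1 is highest with the Trim28 hairpin alone.

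The first comparison asks what 7 days of factor expression did in cells with the control hairpin. Epithelial genes that were almost silent in fibroblasts became abundant: Krt8, a simple-epithelium keratin, went from 0.678 ± 0.277 to 1058 ± 124 CPM (SD, n = 3). Krt8, the tight-junction gene Cldn4 and the membrane protease gene St14 rose by log2 10.59 ± 0.19, 10.18 ± 0.22 and 5.97 ± 0.14 (SE, n = 3 per group). Keratins of stratified epithelium rose on the same scale, with Krt14, Krt16 and Krt17 up by 9.17 ± 0.15, 7.93 ± 0.12 and 11.95 ± 0.20. Fibroblast genes fell, among them Ccdc80, the collagen cross-linking enzyme gene Lox and the contractile gene Tagln with -1.70 ± 0.065, -1.61 ± 0.075 and -1.39 ± 0.083. In all, 9484 of 14520 tested genes (65.3%) changed, 4743 up and 4741 down, and 2061 rose and 1043 fell at least 2-fold.

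Genes with no read in the 3 uninduced libraries headed the rises, so their folds are lower bounds. Krt6b (a stratified-epithelium keratin), Esrp1 (an epithelial splicing regulator) and Prss32 (a serine protease) were at least 909-fold, 801-fold and 717-fold higher after induction. Tdh (threonine dehydrogenase, abundant in mouse embryonic stem cells), Zbtb32 (a zinc finger repressor) and Tspan1 (a tetraspanin) were at least 566-fold, 549-fold and 542-fold higher. Among the falls were Npy6r, a neuropeptide Y receptor gene, the cytokine gene Tnfsf15 and Myocd, a smooth-muscle coactivator, with -3.53 ± 0.48, -3.52 ± 0.34 and -3.38 ± 0.54. The potassium channel gene Kcnd2, the G-protein regulator Rgs4 and Galnt9, a glycosyltransferase gene, followed with -3.26 ± 0.23, -3.19 ± 0.20 and -3.15 ± 0.23.

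Of the epithelial list, 29 of 30 rose and 1 did not pass (29 rose adjusted over the list alone), with a median log2 change of 7.90. Camera called the epithelial list at adjusted p = 1.65e-19, and at adjusted p = 0.0844 with an estimated correlation. In the keratinocyte list 14 of 15 rose and 1 did not pass (14 rose adjusted over the list alone). Camera called the keratinocyte list at adjusted p = 8.88e-10, and at adjusted p = 0.018 with an estimated correlation, so this call held. Of pluripotency network genes, active in embryonic stem cells, 26 of 32 rose, 2 fell and 4 did not pass (26 rose and 2 fell adjusted over the list alone). Camera called the pluripotency list at adjusted p = 3.86e-09, and at adjusted p = 0.0941 with an estimated correlation. L1td1, an RNA-binding protein gene, rose by 10.23 ± 0.23, and Alpl, alkaline phosphatase, by 4.60 ± 0.19. Fgf4, a growth factor gene, was 524-fold (95% counting interval 93.7 to 20700.0) higher on 1 read in uninduced cells. The factor gene Klf5 fell (-0.60 ± 0.19, adjusted p = 0.00992), a call lost without replicate 1 of the uninduced cells at adjusted p = 0.05 (range 0.00146 to 0.05). Nanog, a core pluripotency factor singled out here after its values were seen, went from 0.257 ± 0.173 to 7.37 ± 1.97 CPM. The median of the pluripotency list was 4.71, or 3.84 with its 7 genes of 0 reads in uninduced cells set at their bounds. No other list's median moved in this comparison when such genes were set at their bounds.

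Of mesenchymal genes 30 of 40 fell, 2 rose and 8 did not pass (30 fell and 2 rose adjusted over the list alone), and Dcn, the proteoglycan decorin, rose by 0.86 ± 0.075. Camera called the mesenchymal list at adjusted p = 1.39e-07, and at adjusted p = 0.296 with an estimated correlation. Cell cycle genes moved up together, and in the proliferation list 38 of 40 rose, 1 fell and 1 did not pass (39 rose and 1 fell adjusted over the list alone). Camera called the proliferation list at adjusted p = 1.11e-12, and at adjusted p = 0.138 with an estimated correlation. Mybl2 rose by 3.33 ± 0.13 and the replication helicase genes Mcm5 and Mcm6 by 1.38 ± 0.082 and 1.46 ± 0.088, while E2f1 fell (-0.41 ± 0.12). Of p53 and senescence genes 20 of 30 fell, 4 rose and 6 did not pass (20 fell and 5 rose adjusted over the list alone). Camera called the p53 and senescence list at adjusted p = 0.000992, and at adjusted p = 0.0351 with an estimated correlation, so this call held. The cell cycle inhibitor Cdkn2b and the death receptor Fas changed by -1.52 ± 0.088 and -1.69 ± 0.11. Perp, a desmosome gene that is also in the keratinocyte list, rose by 1.00 ± 0.091. Of the heterochromatin machinery 17 of 34 rose, 1 fell and 16 did not pass (16 rose and 1 fell adjusted over the list alone). Camera called the heterochromatin machinery list at adjusted p = 0.00543, and at adjusted p = 0.296 with an estimated correlation. The imprint-protecting zinc finger gene Zfp57 and the DNA methylation genes Uhrf1 and Dnmt1 led with 1.61 ± 0.081, 1.62 ± 0.094 and 0.87 ± 0.057.

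Markers of other cell types also moved. In the trophoblast list 11 of 13 rose, 1 fell and 1 did not pass (11 rose and 1 fell adjusted over the list alone), with Tead4, Peg10 and Krt7 up by 2.64 ± 0.086, 1.61 ± 0.086 and 3.37 ± 0.19. Camera called the trophoblast list at adjusted p = 6.6e-05, and at adjusted p = 0.0941 with an estimated correlation. Of protocadherins of the beta cluster, cell adhesion genes whose near-identical copies make counts uncertain, 9 of 13 fell and 4 did not pass (9 fell adjusted over the list alone). Camera called the protocadherin list at adjusted p = 0.00938, and at adjusted p = 0.296 with an estimated correlation. Of macrophage markers 4 of 7 rose, 2 fell and 1 did not pass (4 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.162), with the lysosomal gene Laptm5 up by 7.22 ± 0.18. Of endothelial markers 5 of 8 rose, 1 fell and 2 did not pass (5 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0614), with the receptor gene Tek up by 2.64 ± 0.13. The macrophage list was called under the stricter low-count filter (adjusted p = 0.0178, range 0.0178 to 0.524), and the endothelial list without replicate 2 of the induced controls (0.044, range 0.044 to 0.119). They had adjusted p = 0.296 and 0.157 with an estimated correlation. Of neural markers 7 of 11 rose, 2 fell and 2 did not pass (7 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.117), with myelin basic protein Mbp up by 4.96 ± 0.16. Of muscle genes 3 of 8 rose, 3 fell and 2 did not pass (3 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.921), with Mylpf at 3.24 ± 0.29 and Des at -2.13 ± 0.18. The muscle list's median was -0.04 and its mean 0.47. Of primitive endoderm genes 5 of 10 rose, 4 fell and 1 did not pass (5 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.814), with Gata4 at 5.37 ± 0.40 and the collagen gene Col4a1 at -0.91 ± 0.065. All 4 adipocyte markers measured fell (4 fell adjusted over the list alone), among them the lipase Lpl with -2.52 ± 0.14. Lists under 5 tested genes, such as this one, had no set test.

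Of interferon response genes 17 of 39 fell, 10 rose and 12 did not pass (17 fell and 10 rose adjusted over the list alone, camera adjusted p = 0.137). The GTPase Irgm1 and the peptide transporter Tap1 were at -1.23 ± 0.095 and -1.04 ± 0.090, and Bst2 rose by 1.20 ± 0.12. Of imprinted genes 24 of 45 fell, 12 rose and 9 did not pass (26 fell and 12 rose adjusted over the list alone, camera adjusted p = 0.162), with Plagl1 and Meg3 at -1.50 ± 0.10 and -1.21 ± 0.084 and Rtl1 up by 7.83 ± 0.25. The median was negative and the mean positive in both of these lists, at -0.36 and 0.14 for interferon response and at -0.32 and 0.21 for imprinted genes. Of germline genes 8 of 14 rose, 3 fell and 3 did not pass (8 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.162), with Piwil2, which acts in the piRNA pathway, up by 7.23 ± 0.23. Of Zfp genes 88 of 333 rose, 66 fell and 179 did not pass (83 rose and 57 fell adjusted over the list alone, camera adjusted p = 0.729). All 3 two-cell-stage genes tested, of 24 in the deposited table, rose (3 rose adjusted over the list alone). Eif1ad rose by 0.62 ± 0.080 and already stood at 24.0 to 28.9 CPM in the 3 uninduced libraries. Zfp352, another of the 3, was 20-fold (95% counting interval 5.20 to 170.0) higher on 2 reads in uninduced cells.

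Of sex-linked transcripts 2 of 5 fell and 3 did not pass, and no member passed when adjusted over the list alone. The falls of the Y-linked Eif2s3y and Ddx3y (-0.33 ± 0.11 and -0.29 ± 0.12) were lost in 4 and 7 of 13 alternatives (ranges 0.0057 to 0.104 and 0.00256 to 0.181). Both were lost without replicate 1 of the induced controls (adjusted p = 0.0656 and 0.161), without replicate 3 of these (0.0634 and 0.181) and without replicate 3 of the uninduced cells (0.104 and 0.174). Ddx3y was also lost without replicate 2 of the uninduced cells (0.0612). Xist stood between 759 ± 102 CPM in the double knockdown and 1084 ± 119 in the induced controls, and Ddx3y between 41.9 ± 7.17 in the induced controls and 50.8 ± 5.34 in uninduced cells. Of mitochondrial-encoded genes 1 of 10 rose, 1 fell and 8 did not pass (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.814). Of 4 nuclear long noncoding transcripts 3 of 4 fell and 1 did not pass (3 fell adjusted over the list alone), with Neat1 at -0.86 ± 0.070.

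The second comparison asks what the Trim28 hairpin changed in induced cells. A small set of genes that were nearly unread in the controls appeared. Gsdma3, a gasdermin (ENSMUSG00000064224, chromosome 11, 98626360 to 98638226), went from 0.0632 ± 0.0160 to 12.5 ± 1.36 CPM (SD, n = 3), and was 207-fold (95% counting interval 70.4 to 1010.0) higher. Cdhr2, a microvillus cadherin gene (ENSMUSG00000034918, chromosome 13, 54701461 to 54736662), went from 0.0632 ± 0.0160 to 5.50 ± 0.109 CPM, and was 90.7-fold (95% counting interval 30.7 to 442) higher. Each had 3 reads in the controls. The imprinted transcript H19 fell from 3610.0 ± 624 to 1323 ± 195 CPM. In all 3620 genes (24.9%) changed, 1909 up and 1711 down, of which 430 rose and 369 fell at least 2-fold.

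Other large rises were Ceacam10, a cell adhesion gene, the axonemal dynein gene Dnah6 and the sodium channel gene Scn10a, at log2 6.12 ± 0.32, 5.80 ± 0.46 and 5.28 ± 0.22 (SE, n = 3 per group). Clec12a, a myeloid lectin gene, was 57.6-fold (95% counting interval 9.93 to 2310.0) higher on 1 control read. The largest falls were in Aadac, an esterase gene, the trophoblast and heart factor Hand1 (ENSMUSG00000037335, chromosome 11, 57828705 to 57832818) and the testis gene Tsga8, at -4.78 ± 0.31, -4.74 ± 0.47 and -4.61 ± 0.37. Cnksr2, a neuronal scaffold gene, and Ttc29, a sperm flagellum gene, followed with -4.20 ± 0.29 and -4.06 ± 0.31. Abca14, a transporter gene, was 25.2-fold (95% counting interval 8.29 to 125) lower with 3 reads left.

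Cell cycle genes fell. In the proliferation list 25 of 40 fell and 15 did not pass (32 fell adjusted over the list alone) with a median of -0.28. Camera called the proliferation list at adjusted p = 9.93e-09, and at adjusted p = 0.34 with an estimated correlation. The replication licensing gene Cdc6, the mitotic kinesin Kif20a and cyclin B1 (Ccnb1) were at -0.78 ± 0.11, -0.38 ± 0.069 and -0.48 ± 0.094. Of p53 and senescence genes 11 of 30 rose and 19 did not pass (11 rose and 2 fell adjusted over the list alone). Camera called the p53 and senescence list at adjusted p = 0.00441, and at adjusted p = 0.105 with an estimated correlation. Btg2, an antiproliferative p53 target, and Ei24 rose by 0.78 ± 0.056 and 0.49 ± 0.058. Of interferon response genes 10 of 39 rose, 1 fell and 28 did not pass (16 rose and 2 fell adjusted over the list alone). Camera called the interferon response list at adjusted p = 0.00371, and at adjusted p = 0.34 with an estimated correlation. Irgm1, the antiviral Oas2 and the ubiquitin-like Isg15 rose by 0.72 ± 0.096, 1.78 ± 0.24 and 0.96 ± 0.16, and Bst2 was at -0.59 ± 0.11.

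Several lists that had risen with induction were lower with the Trim28 hairpin. In the pluripotency network 13 of 32 fell, 2 rose and 17 did not pass (14 fell and 3 rose adjusted over the list alone). Camera called the pluripotency list at adjusted p = 0.00607, and at adjusted p = 0.475 with an estimated correlation. The call was lost under the stricter low-count filter at adjusted p = 0.0792 (range 7.78e-05 to 0.0792 over 10 alternatives). The Nodal antagonist Lefty2 and Alpl were at -2.54 ± 0.30 and -1.02 ± 0.12, while Fut9, which makes the stem cell antigen SSEA-1, rose by 1.25 ± 0.29. Nanog stood at 5.89 ± 1.49 CPM (adjusted p = 0.343). Of epithelial genes 12 of 30 fell and 18 did not pass (14 fell adjusted over the list alone), the desmosome gene Dsg2, Rab25 and Cldn6 at -1.49 ± 0.15, -1.13 ± 0.16 and -0.88 ± 0.14. Camera called the epithelial list at adjusted p = 0.00371, and at adjusted p = 0.475 with an estimated correlation. Of keratinocyte genes 8 of 15 fell, 1 rose and 6 did not pass (8 fell and 1 rose adjusted over the list alone), Krt6b, Trp63 and Krt13 at -1.57 ± 0.17, -1.63 ± 0.29 and -0.45 ± 0.087 and Sfn up by 0.35 ± 0.085. Camera called the keratinocyte list at adjusted p = 0.00851, and at adjusted p = 0.34 with an estimated correlation. Of trophoblast genes 6 of 13 fell, 2 rose and 5 did not pass (6 fell and 2 rose adjusted over the list alone), Peg10 and Krt7 at -1.66 ± 0.086 and -2.16 ± 0.17. Camera called the trophoblast list at adjusted p = 0.0254, and at adjusted p = 0.357 with an estimated correlation.

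Of protocadherins 5 of 13 fell, 1 rose and 7 did not pass (7 fell and 1 rose adjusted over the list alone), with Pcdhb5 at -1.44 ± 0.27 and Pcdhb22 up by 0.62 ± 0.13. Camera called the protocadherin list at adjusted p = 0.00588, and at adjusted p = 0.357 with an estimated correlation. None of the 8 set calls in the Trim28 knockdown held at an adjusted p under 0.05 with an estimated correlation. The p53 and keratinocyte lists then had unadjusted p = 0.00554 and 0.0474 by camera, and the other 6 lay above 0.05.

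Mesenchymal genes went both ways with the Trim28 hairpin, as 16 of 40 fell, 10 rose and 14 did not pass (19 fell and 10 rose adjusted over the list alone, camera adjusted p = 0.135). Dcn, Lox and the collagen gene Col3a1 were at -0.97 ± 0.076, -0.84 ± 0.074 and -1.30 ± 0.13, and Tagln rose by 1.096 ± 0.082. The mesenchymal list was called without replicate 2 of the induced controls (adjusted p = 0.0349) or replicate 1 of the Trim28 knockdown (0.0268, range 0.0268 to 0.674), and had adjusted p = 0.799 with an estimated correlation. Of imprinted genes 15 of 45 fell, 8 rose and 22 did not pass (15 fell and 8 rose adjusted over the list alone, camera adjusted p = 0.0908), and the list was called without replicate 1 of the Trim28 knockdown (adjusted p = 0.0429, range 0.0429 to 0.229, and adjusted p = 0.475 with an estimated correlation). Peg10 and H19 were at -1.66 ± 0.086 and -1.45 ± 0.13, and Nnat, a membrane proteolipid gene, rose by 1.15 ± 0.19. Within the heterochromatin machinery 7 of 34 fell, 4 rose and 23 did not pass (9 fell and 4 rose adjusted over the list alone, camera adjusted p = 0.306). The chromatin assembly gene Chaf1b, Dnmt3a and Atf7ip, a nuclear partner of Setdb1, changed by -0.61 ± 0.095, -0.45 ± 0.072 and -0.40 ± 0.071, and Atf7ip2 rose by 1.93 ± 0.17. Of germline genes 4 of 14 rose, 2 fell and 8 did not pass (4 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.874), among them Piwil2 and Tdrd9 of the piRNA pathway at 0.91 ± 0.12 and 1.36 ± 0.20. The germline median was -0.03 and the mean 0.01. Of Zfp genes 28 of 333 rose, 13 fell and 292 did not pass (19 rose and 9 fell adjusted over the list alone, camera adjusted p = 0.598), with Zfp109, Zfp454 and the retroviral repressor Zfp809 up by 1.77 ± 0.16, 1.61 ± 0.17 and 0.70 ± 0.11.

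**Figure D2:**
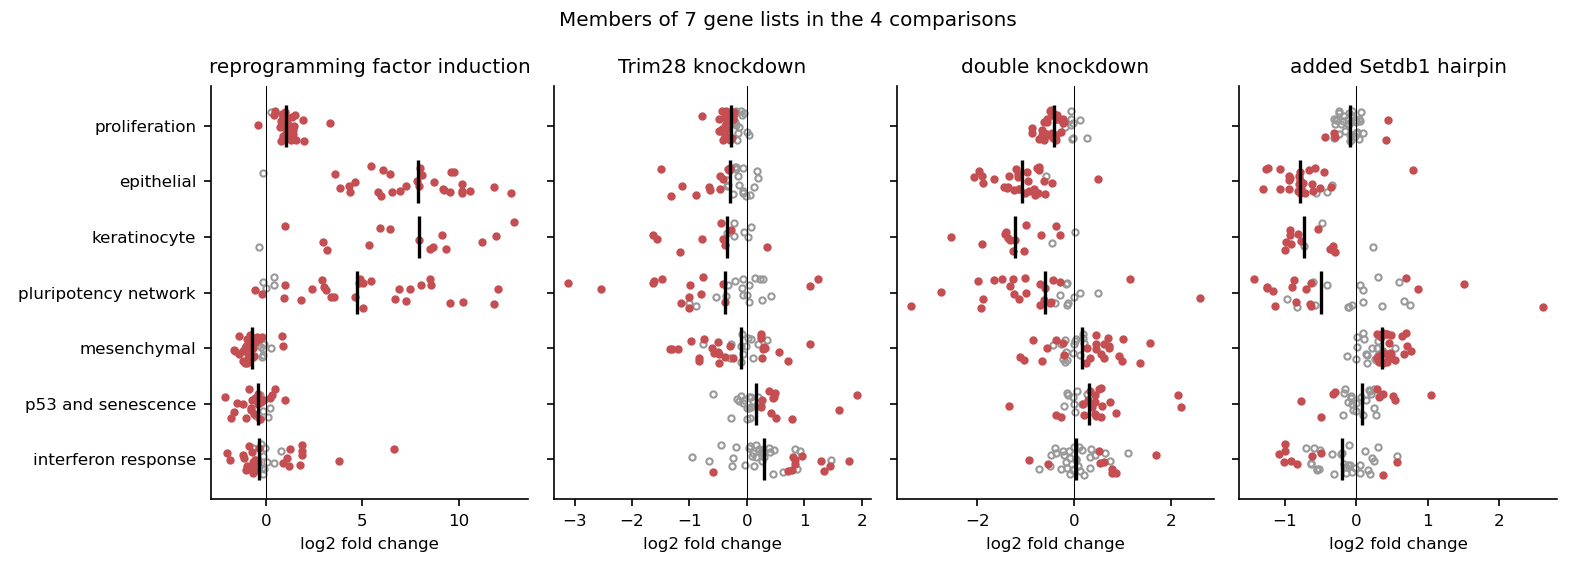
Log2 fold change (x axis, whose range differs between panels) of each tested member of 7 gene lists in the 4 comparisons, filled where the adjusted p was under 0.05 and open otherwise, with list medians as bars. Medians of the epithelial list are 7.90 with induction, -0.29 with the Trim28 hairpin, -1.07 with both hairpins and -0.78 for the added Setdb1 hairpin.

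The third comparison asks what both hairpins together changed in induced cells. Epithelial genes fell with few exceptions, the simple-epithelium keratin Krt18, Dsg2 and Rab25 with log2 -1.64 ± 0.13, -1.90 ± 0.15 and -2.07 ± 0.17 (SE, n = 3 per group). Stratified-epithelium keratins fell with them, Krt16, Krt6a and Krt13 at -1.21 ± 0.073, -1.42 ± 0.091 and -1.37 ± 0.089. The contractile genes Tagln and Acta2 rose by 1.58 ± 0.083 and 1.36 ± 0.10. The cytokine gene Il6 rose by 2.15 ± 0.20 to 8.41 ± 1.76 CPM (SD, n = 3). In all 5322 genes (36.7%) changed, 2633 up and 2689 down, of which 469 rose and 565 fell at least 2-fold.

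Gsdma3 and Cdhr2 were again among the largest rises, 205-fold (95% counting interval 69.7 to 995) and 87.5-fold (95% counting interval 29.6 to 427) higher. Clec12a was 113-fold (95% counting interval 19.9 to 4490.0) higher, and Ceacam10 rose by log2 6.81 ± 0.29. Akr1c21, a hydroxysteroid dehydrogenase gene unread in the controls, was at least 24.4-fold higher. Prrt3, a gene of a proline-rich transmembrane protein, was 73.8-fold (95% counting interval 20.1 to 615) higher on 2 control reads. Among the largest falls were AU015836, Hand1, the desmosome gene Dsg1a and Trim42 at -4.88 ± 0.43, -4.07 ± 0.43, -3.90 ± 0.32 and -3.77 ± 0.60.

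In the epithelial list 28 of 30 fell, 1 rose and 1 did not pass (29 fell and 1 rose adjusted over the list alone), the rise being P-cadherin (Cdh3) by 0.50 ± 0.10. Camera called the epithelial list at adjusted p = 2.63e-13, and at adjusted p = 0.15 with an estimated correlation. In the keratinocyte list 13 of 15 fell and 2 did not pass (13 fell adjusted over the list alone). Camera called the keratinocyte list at adjusted p = 5.93e-07, and at adjusted p = 0.0356 with an estimated correlation, so this call held. Of the pluripotency network 21 of 32 fell, 2 rose and 9 did not pass (21 fell and 3 rose adjusted over the list alone). Camera called the pluripotency list at adjusted p = 2.57e-05, and at adjusted p = 0.206 with an estimated correlation. The factor gene Tfcp2l1, Lefty2 and the methyltransferase gene Dnmt3b were at -1.93 ± 0.16, -3.37 ± 0.33 and -1.66 ± 0.17, and Nanog stood at 2.63 ± 0.823 CPM (-1.48 ± 0.26). Tex19.1, which is also a germline gene, rose by 2.60 ± 0.39. Of trophoblast genes 9 of 13 fell, 1 rose and 3 did not pass (9 fell and 1 rose adjusted over the list alone), among them Krt7 and Wnt7b at -1.87 ± 0.17 and -2.25 ± 0.22, with Eomes up by 1.69 ± 0.29. Camera called the trophoblast list at adjusted p = 0.00017, and at adjusted p = 0.15 with an estimated correlation. Of proliferation genes 31 of 40 fell and 9 did not pass (32 fell and 1 rose adjusted over the list alone), with Cdc6, Mybl2 and Kif23 at -0.88 ± 0.11, -0.88 ± 0.11 and -0.55 ± 0.079. Camera called the proliferation list at adjusted p = 2.57e-09, and at adjusted p = 0.206 with an estimated correlation. Of p53 and senescence genes 17 of 30 rose, 3 fell and 10 did not pass (19 rose and 3 fell adjusted over the list alone), with the stress kinase Plk2 up by 0.51 ± 0.059 and the growth factor binding protein Igfbp5 at -1.35 ± 0.23. Camera called the p53 and senescence list at adjusted p = 0.0012, and at adjusted p = 0.0356 with an estimated correlation, so this call held too.

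The other 3 set calls were each lost under at least 1 alternative. Of Zfp genes 70 of 333 fell, 24 rose and 239 did not pass (55 fell and 17 rose adjusted over the list alone). Camera called the zinc finger list at adjusted p = 0.018, and at adjusted p = 0.51 with an estimated correlation. This call was lost without replicate 2 of the induced controls at adjusted p = 0.123 (range 0.00403 to 0.123). Zfp57, Zfp354c and Zfp217 changed by -0.50 ± 0.077, -0.67 ± 0.11 and -0.42 ± 0.069, while Zfp558 (ENSMUSG00000074500, chromosome 9, 18455575 to 18478268) rose by 3.50 ± 0.16, from 2.40 ± 0.733 to 26.5 ± 3.24 CPM. Of macrophage markers 3 of 7 fell and 4 did not pass (3 fell adjusted over the list alone), Itgam, Cd68 and Csf1r at -1.12 ± 0.19, -0.85 ± 0.16 and -1.03 ± 0.20. Camera called the macrophage list at adjusted p = 0.0474, and at adjusted p = 0.206 with an estimated correlation. Of protocadherins 6 of 13 fell, 1 rose and 6 did not pass (7 fell and 1 rose adjusted over the list alone), Pcdhb21 at -1.19 ± 0.29. Camera called the protocadherin list at adjusted p = 0.0474, and at adjusted p = 0.457 with an estimated correlation. The macrophage and protocadherin calls were each lost in 6 of 10 alternatives (ranges 0.0285 to 0.0727 and 0.00128 to 0.154). Both were lost without replicate 1 of the induced controls (adjusted p = 0.0727 and 0.154), replicate 2 of these (0.0542 and 0.0542) or replicate 2 of the double knockdown (0.0578 and 0.0789). The macrophage call was also lost without replicate 1 of the double knockdown (0.0631), and the protocadherin call without its replicate 3 (0.0936).

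In the mesenchymal list 17 of 40 rose, 8 fell and 15 did not pass (17 rose and 10 fell adjusted over the list alone, camera adjusted p = 0.0632). This list was called in 4 of 10 alternatives (range 0.00644 to 0.174), without the low-count filter (adjusted p = 0.0302), replicate 1 of the induced controls (0.00644) or replicate 2 or 3 of the double knockdown (0.045 and 0.0212). It had adjusted p = 0.722 with an estimated correlation. Ccdc80 rose by 1.00 ± 0.064 and Col3a1 fell (-1.04 ± 0.13). Of interferon response genes 7 of 39 rose, 2 fell and 30 did not pass (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.385), with Irgm1 and Tap1 up by 0.62 ± 0.096 and 0.51 ± 0.091. Of imprinted genes 17 of 45 fell, 11 rose and 17 did not pass (17 fell and 13 rose adjusted over the list alone, camera adjusted p = 0.52), with Peg10, Mest and H19 at -1.24 ± 0.084, -2.26 ± 0.20 and -1.43 ± 0.13 and Nnat up by 2.32 ± 0.17. Of germline genes 6 of 14 rose, 1 fell and 7 did not pass (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0957), with Tdrd9 and the meiotic cohesin gene Stag3 up by 1.69 ± 0.20 and 1.02 ± 0.19. In the heterochromatin machinery 12 of 34 fell, 5 rose and 17 did not pass (13 fell and 5 rose adjusted over the list alone, camera adjusted p = 0.0957). Dnmt3a and Uhrf1 were at -0.63 ± 0.072 and -0.58 ± 0.089, and 2810474O19Rik, the symbol used in the table for Resf1, rose by 1.53 ± 0.096. The heterochromatin list was called without the low-count filter (adjusted p = 0.0462) or replicate 1 of the induced controls (0.0448, range 0.0448 to 0.251), and had adjusted p = 0.605 with an estimated correlation. All 3 two-cell-stage genes tested, of 24 in the deposited table, fell (3 fell adjusted over the list alone), Eif1ad with -0.29 ± 0.078. The call of Zfp352 was lost in 2 of 12 alternatives, without replicate 3 of the induced controls (adjusted p = 0.0703) or replicate 1 of the double knockdown (0.0614, range 0.00966 to 0.0703). That of Sp110 was lost in 8 of 12 (range 0.0168 to 0.263), among them without replicate 2 or 3 of the induced controls (adjusted p = 0.054 and 0.263) and without replicate 1 or 3 of the double knockdown (0.137 and 0.132). With the replicate number as a block it was also lost (-1.11 on the log2 scale, adjusted p = 0.0529).

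**Figure D3:**
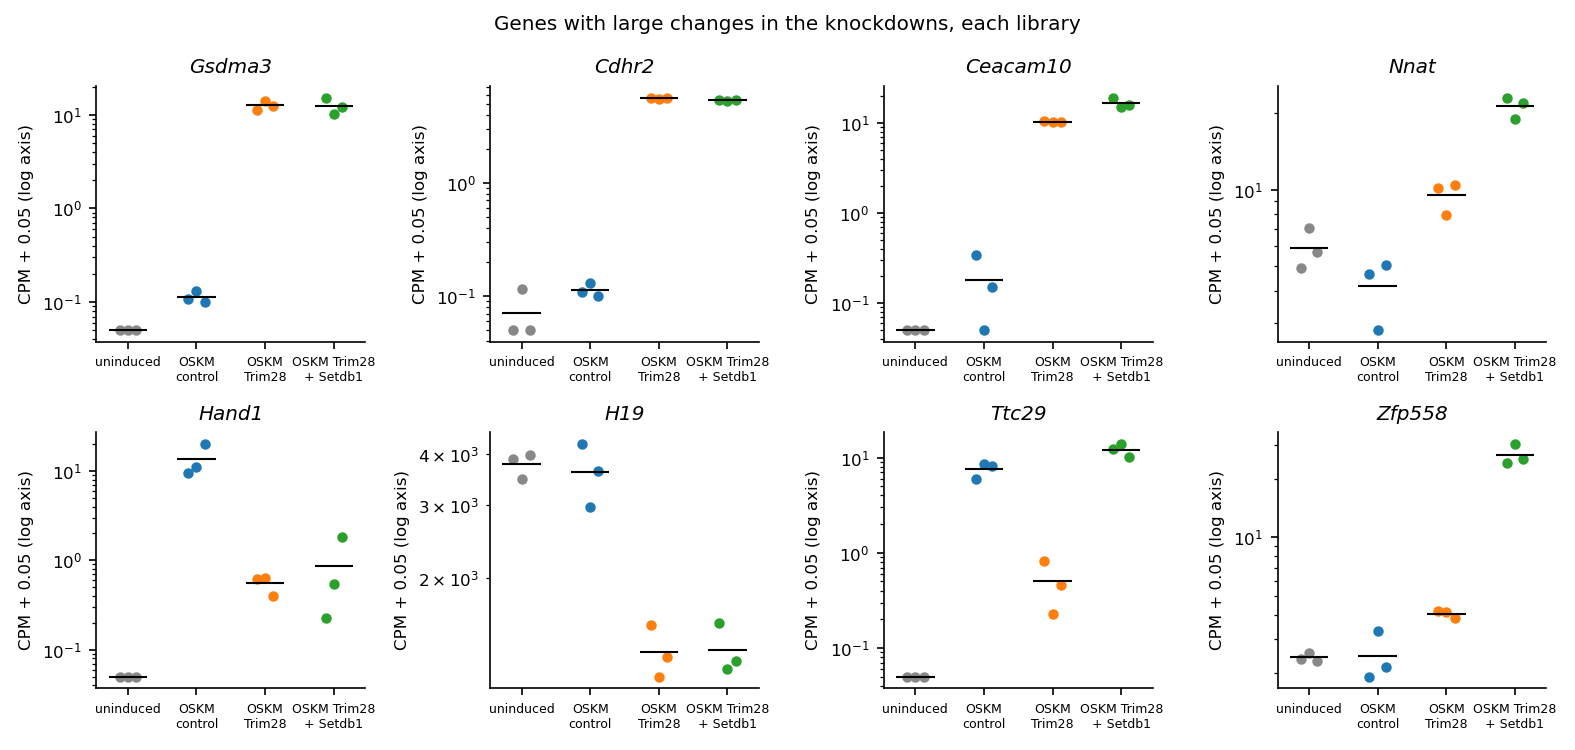
CPM plus 0.05 on a log axis in each library (points, 3 per group) for 8 genes named in the text, with group means as bars. Gsdma3 goes from 0.0632 ± 0.0160 CPM in the induced controls to 12.5 ± 1.36 with the Trim28 hairpin and 12.5 ± 2.54 with both, while Ttc29 is low only in uninduced cells (0 CPM) and with the Trim28 hairpin alone (0.449 ± 0.294 CPM, SD).

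The fourth comparison, both hairpins against the Trim28 hairpin alone, shows what changed when the Setdb1 hairpin was added. Most epithelial genes were lower, Krt18, the epithelial regulator Grhl2 and Cldn4 by log2 -1.24 ± 0.13, -1.30 ± 0.14 and -0.94 ± 0.10 (SE, n = 3 per group). Fibroblast genes were higher, Dcn, Lox and Ccdc80 by 0.77 ± 0.075, 0.71 ± 0.074 and 0.44 ± 0.063. Ttc29 (ENSMUSG00000037101, chromosome 8, 78213297 to 78394326) rose from 0.449 ± 0.294 to 12.02 ± 1.87 CPM (SD, n = 3), and Zfp558 reached 26.5 ± 3.24. In all 3154 genes (21.7%) changed, 1452 up and 1702 down, with 133 rising and 239 falling at least 2-fold. The count was 4849 when only these 2 groups were fitted and 4784 without the 2 libraries of highest mitochondrial share, which belong to other groups. It was 1829, 2063 and 1853 without replicate 2 or 3 of the Trim28 knockdown or replicate 1 of the double knockdown.

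The largest rises were Ttc29, Tsga8, the pancreatic lipase relative Pnliprp2, the choline transporter relative Slc44a5, Akr1c21 and Zfp558. Their log2 changes were 4.74 ± 0.29, 4.52 ± 0.37, 4.42 ± 0.32, 3.42 ± 0.39, 2.99 ± 0.42 and 2.73 ± 0.14. The largest falls were AF529169, the suprabasal keratin Krt1, the neutrophil protein gene S100a9, endothelial nitric oxide synthase Nos3 and the blood cell gene Hemgn, at -2.98 ± 0.36, -2.59 ± 0.27, -2.56 ± 0.29, -2.55 ± 0.43 and -2.14 ± 0.36. Thyrotropin-releasing hormone (Trh) was at -2.37 ± 0.61 (adjusted p = 0.0112), a call lost without replicate 2 of the Trim28 knockdown, where the log2 change was -1.34 at adjusted p = 0.106 (range 1.81e-15 to 0.106).

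In the epithelial list 26 of 30 fell, 1 rose and 3 did not pass (28 fell and 1 rose adjusted over the list alone), Cdh3 again being the rise at 0.79 ± 0.10. Camera called the epithelial list at adjusted p = 8.33e-13, and at adjusted p = 0.323 with an estimated correlation. Of mesenchymal genes 23 of 40 rose and 17 did not pass (26 rose adjusted over the list alone). Camera called the mesenchymal list at adjusted p = 6.34e-10, and at adjusted p = 0.432 with an estimated correlation. Of keratinocyte genes 12 of 15 fell and 3 did not pass (12 fell adjusted over the list alone), with Krt16, Krt6a and Krt13 at -0.93 ± 0.073, -0.99 ± 0.091 and -0.91 ± 0.089. Camera called the keratinocyte list at adjusted p = 6.17e-06, and at adjusted p = 0.0887 with an estimated correlation. Of Zfp genes 51 of 333 fell, 7 rose and 275 did not pass (45 fell and 7 rose adjusted over the list alone), with Zfp704, Zfp57 and Zfp141 at -0.66 ± 0.084, -0.58 ± 0.077 and -1.03 ± 0.15. Camera called the zinc finger list at adjusted p = 0.000151, and at adjusted p = 0.432 with an estimated correlation. Of interferon response genes 8 of 39 fell, 2 rose and 29 did not pass (9 fell and 3 rose adjusted over the list alone), with Irf7 and Oas2 at -0.99 ± 0.17 and -0.91 ± 0.21. Camera called the interferon response list at adjusted p = 0.0269, and at adjusted p = 0.432 with an estimated correlation. This call was lost without replicate 3 of the Trim28 knockdown at adjusted p = 0.099 (range 0.00225 to 0.099). None of the 5 set calls passed with an estimated correlation, where epithelial and keratinocyte genes had unadjusted p = 0.034 and 0.00467 by camera and the others lay above 0.05.

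Whether the pluripotency, proliferation and germline lists were called in this comparison depended on the setting. In the pluripotency network 12 of 32 fell, 4 rose and 16 did not pass (13 fell and 4 rose adjusted over the list alone, camera adjusted p = 0.064). Tet2, Nr5a2 and Tfcp2l1 were at -0.84 ± 0.095, -1.43 ± 0.18 and -1.13 ± 0.17, and Alpl rose by 0.87 ± 0.12. Of proliferation genes 3 of 40 fell, 2 rose and 35 did not pass (2 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.064). The pluripotency and proliferation lists were each called in 6 of 10 alternatives (ranges 0.0108 to 0.129 and 0.0109 to 0.472). Both were called without the low-count filter (adjusted p = 0.0393 and 0.0279), with the replicate number as a block (0.0466 for each), without replicate 2 of the Trim28 knockdown (0.0155 and 0.0331), and without replicate 2 (0.0108 and 0.041) or 3 (0.0422 and 0.0109) of the double knockdown. The stricter filter also called the pluripotency list (0.0117), and RLE size factors the proliferation list (0.0465). These lists had adjusted p = 0.564 and 0.706 with an estimated correlation. Of p53 and senescence genes 6 of 30 rose, 4 fell and 20 did not pass (7 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.39), where Plk2 rose by 0.51 ± 0.059 and Btg2 fell (-0.49 ± 0.055). Of the heterochromatin machinery 4 of 34 rose, 3 fell and 27 did not pass (4 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.37), with 2810474O19Rik and Atf7ip, the Setdb1 partner, up by 1.24 ± 0.095 and 0.92 ± 0.071. Of imprinted genes 9 of 45 rose, 7 fell and 29 did not pass (9 rose and 7 fell adjusted over the list alone, camera adjusted p = 0.166), with Nnat up by 1.16 ± 0.16 and Rtl1 at -1.16 ± 0.12. Of germline genes 4 of 14 rose, 2 fell and 8 did not pass (5 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.064), with Tex19.1 and Stag3 up by 2.61 ± 0.39 and 1.08 ± 0.19. RLE size factors called the germline list (adjusted p = 0.0465, range 0.0261 to 0.182), as did leaving out replicate 2 of the Trim28 knockdown (0.0331) or replicate 1 or 3 of the double knockdown (0.0261 and 0.0433). It had adjusted p = 0.418 with an estimated correlation. Of trophoblast genes 4 of 13 fell, 1 rose and 8 did not pass (4 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0976), Elf5 at -1.70 ± 0.21.

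Fold changes of the knockdowns were then set against those of induction across the 14520 tested genes. For the double knockdown Pearson's r was -0.466 (Spearman's rho -0.515), where unchanged groups sharing the control libraries gave -0.067. The covariance was -0.361 against a simulated -0.0167. For the Trim28 knockdown r was -0.129 (rho -0.122) against a simulated -0.0682, with covariances of -0.0894 and -0.0171, and without replicate 1 of the induced controls r was -0.211. A jackknife over the libraries left out gave this r an SD of 0.09, so it cannot be told from the simulated value. The comparison of both hairpins with the Trim28 hairpin alone shares no library with the induction, and its r was -0.531 (rho -0.581, simulated 0.0017). Genes are not independent replicates, so these values have no p.

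Among the 2061 genes that induction raised at least 2-fold, such as Krt8, Cldn4 and L1td1, 935 (45.4%) fell and 46 rose when the Setdb1 hairpin was added. Against the induced controls, 1133 of them fell and 159 rose with both hairpins, and 517 fell and 426 rose with the Trim28 hairpin alone. Among the 1043 genes that induction lowered at least 2-fold, such as Ccdc80, Lox and Tagln, 323 rose and 7 fell with the added Setdb1 hairpin. Of these genes 461 rose and 46 fell in the double knockdown, and 206 rose and 92 fell in the Trim28 knockdown. Camera was adjusted over these 6 set tests. It gave adjusted p = 1.38e-33 and 2.66e-17 for the added hairpin, 1.53e-21 and 2.19e-16 for the double knockdown, and 0.218 and 0.00916 for the Trim28 knockdown. With an estimated correlation none passed. The 4 tests that involve the Setdb1 hairpin then had adjusted p = 0.0544 (unadjusted p = 0.0106 to 0.0363), and those of the Trim28 knockdown adjusted p = 0.747 and 0.529. The sets were chosen on the induced controls and uninduced cells. The 2 comparisons against the induced controls share those controls with them, and that of the added hairpin shares no library.

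The knockdowns shared many changed genes. With the Trim28 hairpin and with both hairpins, 1190 genes rose, among them Gsdma3, Cdhr2 and Nnat, and 1147 fell, among them Hand1, H19 and Cdc6. Independent lists of these sizes would share 346 and 317. In 10 simulated fits of unchanged groups, 0.7 and 1 genes were called on average and 0.1 in both, too few to gauge what shared controls add to an overlap of such long lists. The fold changes correlated with r = 0.763 (rho 0.650), against 0.512 for unchanged groups that share the controls, and with a covariance of 0.225 against 0.0171. Part of the excess may come from the shared controls, which were too few to split. Of the 2337 genes called in the same direction in both, 1765 did not pass the test of the difference between the knockdowns.

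**Figure D4:**
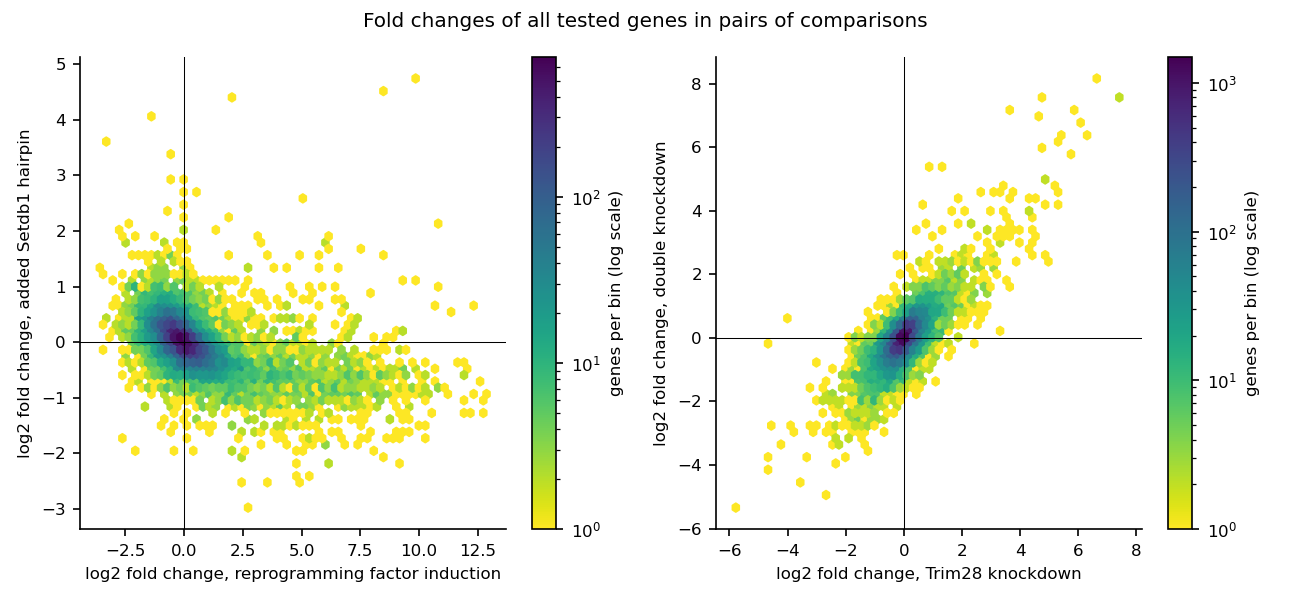
Log2 fold changes of the 14520 tested genes in pairs of comparisons, as hexagonal bins coloured by the number of genes on a log scale. Left, the added Setdb1 hairpin (y axis) against induction (x axis), r = -0.531, and right, the double knockdown (y axis) against the Trim28 knockdown (x axis), r = 0.763, where both share the control libraries.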

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

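The tests on the factors and on genes that they switched on were chosen only after the results were seen, while the splits of the libraries were planned.

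Beside the 2337 genes called in the same direction, 75 genes changed in opposite directions with the Trim28 hairpin and with both hairpins. Of these, 53 were higher with the Trim28 hairpin and lower with both, and 22 the other way round. All 75 passed the edgeR test of the difference, which opposite calls against the same controls nearly ensure, so that test adds no support for them. Setdb1 itself and Atf7ip are among them. The difference between the knockdowns was 4.74 on the log2 scale for Ttc29. It stood at 7.53 ± 1.37 CPM (SD, n = 3) in the induced controls, 0.449 ± 0.294 with the Trim28 hairpin and 12.02 ± 1.87 with both hairpins. The difference was -2.59 for the suprabasal keratin Krt1, at 1.51 ± 0.155, 3.45 ± 0.682 and 0.574 ± 0.212 CPM in induced controls, Trim28 knockdown and double knockdown. For the endothelial receptor Tie1 it was -1.65, with 3.73 ± 0.219, 7.15 ± 0.517 and 2.28 ± 0.444 CPM in the same order, and for the imprinted Rtl1 -1.16, with 40.4 ± 4.02, 50.8 ± 6.48 and 22.7 ± 2.95 CPM.

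Of 57 genes that the factors switched on, with at most 3 reads in uninduced cells and at least 10 CPM in the induced controls, 41 fell when the Setdb1 hairpin was added, 3 rose (among them Gabrp and Pou4f2, named after their values were seen) and 13 did not pass, with a median log2 change of -0.78. A larger share of cells that do not express the factors would lower them by 1 common ratio, if cells with the hairpins alone, which were not analysed here, do not express them, and genes that the Trim28 hairpin moved may break this condition. Among the 25 of these genes that the Trim28 hairpin did not change by the edgeR test, 23 fell and their changes spread by an SD of 0.263 beyond their own error (95% bootstrap interval 0.169 to 0.324), against 0.487 (0.336 to 0.613) over all 57 genes. An exactly common ratio would leave no spread beyond error, and the whole interval of the 25 lies above that. It also includes the limit of 0.25, set after the data were seen, which the interval of the 57 exceeds. The test cannot decide, because genes among the 25 may have moved with the Trim28 hairpin without passing. Such cells thus stay open as the whole cause, as do lower levels of the 4 factors per cell. The median change of the factors, -0.64, lay at percentile 69.8 of medians of 4 random switched-on genes, inside the limits of 5 and 95. The design also leaves open, as untested, the loss of Setdb1 itself and the weaker knockdown of Trim28 in those libraries (103 ± 6.41 against 58.5 ± 5.95 CPM). The deposited names give a single hairpin label per target, and no group had the Setdb1 hairpin alone. Effects of a hairpin other than the loss of its target therefore cannot be told from that loss in any knockdown comparison.

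Of 40 cell cycle genes 25 fell with the Trim28 hairpin and 15 did not pass, with a median of -0.28 (adjusted p = 0.34 by camera with an estimated correlation). A larger share of uninduced cells would lower the 4 factors, which induction raised by more than the median of this list, at least as far. This holds only if the Trim28 hairpin left the factors' transcripts per cell unchanged, which was not tested. The log2 changes of the 4 factors less 2 SE were at -0.112 or higher, above the 95% bootstrap interval of the list's median (-0.338 to -0.233). On that condition these values argue against such cells as the whole cause. The 57 switched-on genes had a median of -0.355, and 27 fell and 5 rose, which goes with such cells. They were chosen by their level in the induced controls, the reference here, which can tilt them towards falling by an amount not estimated. A larger share of non-dividing cells that express the factors and an effect of Trim28 loss on division stay open, both untested.

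Each count of changed genes was set against the other splits of its 6 libraries into 3 and 3. The real split, 1 of 10 in each comparison, called 9484, 3620, 5322 and 3154 genes in induction, Trim28 knockdown, double knockdown and added Setdb1 hairpin, and the highest other split 0, 1, 0 and 0. In the double knockdown the 3 other splits that part as many same-numbered pairs, like the rest, called 0. With 10 splits a share under 0.05 cannot be reached. Every other split also mixes libraries of both real groups, so a real difference widens the spread within its groups. Low counts in those splits were therefore built in, and the contrast does not tell a real difference from chance.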

How the results depend on the processing

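The alternative that leaves out the 2 libraries with the highest mitochondrial share was chosen after seeing the data, and all other alternatives were planned. No list call, relation or call of a named gene changed direction under any alternative run. Requiring a fold change of 2 left 3104, 799, 1034 and 372 genes in induction, Trim28 knockdown, double knockdown and added Setdb1 hairpin, by construction of that threshold. The count for the added Setdb1 hairpin was higher by more than 1.5 times in 2 settings. It was 4849 with only these 2 groups in the fit, where the other counts, each from its own 2 groups, were 8275, 3161 and 4270. Without the 2 libraries of highest mitochondrial share it was 4784, where the other counts were 9539, 4476 and 5697. In both settings more genes were called for the added hairpin than for the Trim28 knockdown, the reverse of the main fit. The main fit gives each gene 1 spread shared by the 4 groups. Replicates differed by a chi-square per degree of freedom of 9.67 to 18.8 in the induced controls and 1.96 to 14.2 in uninduced cells. In the Trim28 knockdown and the double knockdown it was 2.02 to 3.35 and 5.38 to 5.96. Whether this unequal spread is the cause was not tested, and the counts do not rank the sizes of the effects. Leaving out 1 library at a time gave 8647 to 9544, 2502 to 3741, 3989 to 5666 and 1829 to 2843 genes, with fewer samples in each fit. The last count was lower than in the main fit by more than 1.5 times in some of these fits. It was 1829 and 2063 without replicate 2 or 3 of the Trim28 knockdown and 1853 without replicate 1 of the double knockdown. Other normalization, tools and filters kept every count of genes within 1.5 times.

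Of the set calls, 9, 8, 9 and 5 in the 4 comparisons, an estimated correlation kept 2, 0, 2 and 0. For the added Setdb1 hairpin 8 lists were called without a low-count filter, and leaving out libraries gave 4 to 8, the 8 without replicate 2 of the Trim28 knockdown or replicate 3 of the double knockdown. In the other comparisons these ranges were 9 to 10, 8 to 10 and 6 to 9, the 6 without replicate 2 of the induced controls. The cause was not tested. The relation of the added hairpin to induction was -0.435 without the filter, which tests more genes of low count, and -0.554 to -0.439 with libraries left out. For the Trim28 knockdown the range was -0.211 to -0.0954, with -0.211 without replicate 1 of the induced controls, and for the double knockdown -0.518 to -0.413. For the overlap of the knockdowns r ran from 0.74 to 0.786, with 859 to 1233 genes rising and 854 to 1373 falling in both.

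With the replicate number as a block, 9572, 3864, 5537 and 3399 genes and 9, 8, 9 and 7 lists were called, the 2 added lists for the Setdb1 hairpin being the pluripotency network and proliferation, and no other list call changed. In that comparison 1 of 3 pairs of same-numbered libraries correlated over 0.1, but all 3 were above 0 (0.032 to 0.191). Whether the numbers pair its samples stays undecided. In the double knockdown, where the numbers were taken to pair the samples, the block changed no list call and 5 of 204 calls of named genes. Those of Sp110 and Kcnd2 were lost in the edgeR test (adjusted p = 0.0529 and 0.0591), and Klf5, Stmn2 and Zfp704 were gained (0.0299, 0.0434 and 0.0379). Over all comparisons 6 of 18 pairs of libraries with the same number correlated over 0.1 (range -0.224 to 0.31, highest between other numbers 0.386), and the 9 pairs among the 3 induced groups were all above 0 (0.032 to 0.31). As a hint from the data, 8 of 12 libraries correlated best with their own number. Of 351 calls of named genes, 36 were lost under at least 1 alternative. Without the low-count filter edgeR's prior degrees of freedom became infinite (8.04 with it), so its p-values there rest on the trend over genes alone. At these depths genes under 0.156 to 0.252 CPM cannot be told from 0 in 1 library.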

Other observations

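Of the tests in this part, the count of silent genes and its limits were chosen only after the data were seen, as were the genes named as examples of silent, switched-off and neighbouring genes.

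Markers of other lineages moved in both directions in the knockdowns. The neural growth-cone gene Gap43 rose from 16.7 ± 0.977 CPM (SD, n = 3) in the induced controls to 45.1 ± 2.57 with the Trim28 hairpin and 73.9 ± 2.08 with both, log2 changes of 1.43 ± 0.083 and 2.14 ± 0.082 (SE, n = 3 per group), while the microtubule gene Map2 fell by the same test (-0.87 ± 0.10 and -1.31 ± 0.10). In the neural list 4 of 11 rose, 3 fell and 4 did not pass with the Trim28 hairpin (4 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.682). With both hairpins 4 of 11 rose, 3 fell and 4 did not pass (5 fell and 4 rose adjusted over the list alone, camera adjusted p = 0.6), and for the added Setdb1 hairpin 3 of 11 rose, 2 fell and 6 did not pass (3 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.733). The neural medians were 0.39 and 0.15 in these last comparisons and the means -0.04 and -0.10. The skeletal actin Acta1 rose by 1.29 ± 0.15 and 1.92 ± 0.15. Of muscle genes 2 of 8 rose, 1 fell and 5 did not pass with the Trim28 hairpin (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.314), and 2 of 8 rose, 1 fell and 5 did not pass with both (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.52). For the added hairpin 2 of 8 rose, 2 fell and 4 did not pass (2 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.759), with a median of 0.28 and a mean of -0.01. Of endothelial genes 3 of 8 rose and 5 did not pass with the Trim28 hairpin (3 rose adjusted over the list alone, camera adjusted p = 0.902), with a median of -0.15, a mean of -0.01 and an upward camera direction. With both hairpins 3 of 8 fell, 1 rose and 4 did not pass (3 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.125), the receptor Flt1 at -0.75 ± 0.12, and for the added hairpin 4 of 8 fell and 4 did not pass (4 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.224).

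Of primitive endoderm genes 2 of 10 fell, 1 rose and 7 did not pass with the Trim28 hairpin (2 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.353). With both hairpins 4 of 10 fell, 3 rose and 3 did not pass (4 fell and 3 rose adjusted over the list alone, camera adjusted p = 0.86), with a median of 0.11, a mean of -0.12 and a downward camera direction. For the added hairpin 3 of 10 rose, 1 fell and 6 did not pass (4 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.293). Apolipoprotein Apob rose by 0.81 ± 0.17 and 1.40 ± 0.17 in the 2 knockdowns, and Pdgfra was at -1.21 ± 0.12 and -0.84 ± 0.12. Of 4 adipocyte genes, 1 rose and 1 fell in each knockdown (1 rose and 3 fell, and 1 rose and 1 fell, adjusted over the list alone). The adipogenic factor Pparg was at -1.61 ± 0.24 and -1.30 ± 0.23. Of macrophage markers 2 of 7 fell and 5 did not pass with the Trim28 hairpin (3 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0908), led by Csf1r at -1.33 ± 0.21. That list was called without the low-count filter (adjusted p = 0.000166) or replicate 3 of the Trim28 knockdown (0.0388, range 0.000166 to 0.18), and had adjusted p = 0.34 with an estimated correlation. Of 10 mitochondrial-encoded genes, 1 fell with both hairpins, mt-Co1 at -0.31 ± 0.079 (1 fell adjusted over the list alone, camera adjusted p = 0.339). For the added hairpin this list had a median of 0.00574 and a mean of -0.00612 (camera adjusted p = 0.9). Of 4 nuclear long noncoding transcripts, 1 rose with the Trim28 hairpin and none fell. For the added hairpin 1 rose and 2 fell, and with both hairpins 1 rose and 2 fell. Malat1 was at -0.35 ± 0.094 with both hairpins. Xist, at -0.52 ± 0.094, was then the 1 sex-linked transcript called of 5 (1 fell adjusted over the list alone).

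Some genes went from near silence to measurable levels. With mean CPM under 0.2 in the uninduced cells and the induced controls, 31 genes reached at least 1 CPM in the Trim28 knockdown and 28 in the double knockdown, 17 of them in both and 42 in either, 12 of these outside the protein-coding class. Besides Gsdma3, Ceacam10, Cdhr2 and Dnah6 they include the blood group transferase gene Abo, at 3.53 ± 0.486 and 3.45 ± 0.424 CPM in the 2 knockdowns, and Pnliprp2, at 0.356 ± 0.208 and 7.88 ± 0.917. The test the other way, from at least 1 CPM in both control groups to under 0.2, found 0 genes with the Trim28 hairpin and 1 with both, Scrg1, at 3.08 ± 0.814 CPM in uninduced cells, 1.35 ± 0.671 in the induced controls and 0.190 ± 0.0236 with both hairpins.

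Genes that rose at least 2-fold in both knockdowns often sat next to each other. Among these 266 genes 21 pairs of next-door tested genes within 100 kb were both in the set, against a mean of 3.81 and a 95th percentile of 7 in 10000 random sets matched on expression (permutation p = 1e-04, the smallest these sets can give). Without pairs whose models overlap in the deposited coordinates or whose symbols share a stem, 15 pairs were left (random mean 2.72, 95th percentile 6). This argues against shared reads of models that overlap in those coordinates as the whole cause. Reads shared across short gaps are not covered, because such pairs were kept. The random sets were not matched on gene density. The pairs include Cdhr2, Gprin1, Eif4e1b and Tspan17 in a line on chromosome 13, with gaps of 9, 34124 and 918 bp. Others are Gpr1 and Zdbf2 on chromosome 1, and Rpl39l and Atf7ip2 on chromosome 16. The 246 genes that fell at least 2-fold in both, counted in the same way, gave 5 pairs (permutation p = 0.09). Regional loss of silencing is a candidate explanation, read-through from 1 gene into the next may be another, and neither was tested.

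The same 266 risers held 32 genes outside the protein-coding class (12.03%), against 13 of the 246 fallers (5.29%) and 5.74% of all tested genes (Fisher's exact test of risers against fallers, two-sided, p = 0.00771).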
